A study of Cereibacter sphaeroides 2.4.1 with 6 samples.

How the data were processed

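Cells labelled as lacking ChrR were fixed with formaldehyde, their DNA was sheared and digested with a nuclease, and fragments bound by RpoE or by the Beta' subunit of RNA polymerase were recovered with polyclonal sera, per the labels' protocols. ChIP DNA was amplified by ligation-mediated PCR before labelling, per the labels' protocols. ChIP DNA carried Cy5 and input DNA Cy3 on all 6 arrays, with no dye swap, so dye effects stay in every ratio. There were 3 arrays per antibody, grouped by the labels.

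The deposited scanner files hold an intensity per probe and channel, extracted with NimbleScan 2.4.31 for replicates 1 and 2 of both antibodies and NimbleScan 2.3.78 for replicate 3 of both, per the file headers. By version number alone, arrays with 2.4.31 are called the later scans and arrays with 2.3.78 the earlier scans. No background subtraction is stated there. The deposited value table and probe files hold a log ratio of ChIP to input, taken here as log2, which the authors quantile normalized per the file headers. Its values have the same distribution on the 3 arrays of an antibody, with medians of -0.019 for RpoE and -0.053 for Beta'. Against log2 scanner ratios, r over probes was 0.988 and 0.985 for replicate 3 of RpoE and Beta' but 0.793 to 0.887 for the other arrays. Whether a step before the quantile normalization differed by scan is unknown. The log base was inferred from the slope against log2 scanner ratios, which was 0.971 on RpoE replicate 3 but 0.436 to 1.20 over all arrays. The slopes alone do not settle the base, and fold thresholds in the deposited ratios rest on this reading. The direction was that of Cy5 over Cy3, and the centring stays unknown.

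From the scanner intensities, log2 of Cy5 over Cy3 was computed per probe and centred on the median of each array, with no loess or quantile step, since many features of a ChIP array can truly shift one way. The 36226 random control probes were left out of the ratios and used as background. Ratios were averaged over bins of 200 bp with at least 5 probes (median 15), which gave 23016 bins and left out 1. The 6 arrays entered one group-means fit in limma 3.58.1 (R 4.3.3). RpoE against 0, Beta' against 0 and RpoE against Beta' were tested with treat against a 1.5-fold change, with Benjamini-Hochberg adjustment over all bins and a threshold of 0.05. Called bins with a gap of at most 1 bin formed regions of at least 2 bins. Tested on simulated data with the arrays' spread over 23016 bins, the RpoE test recovered 0 of 200 raised bins at a log2 ratio of 1, 95.5% at 2 and 98.5% at 3, with 0 false calls. The raised bins were drawn at random and kept their own fitted spread, not the spread of the RpoE sites.

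The rule for named features, fixed before the data were examined, took the 15 RpoE regions with the highest summits among those called. With no call, it named none. In its place, after the data were examined, bins in the highest 1% of every array of an antibody were taken and joined by the same gap rule, with chance set by 10000 circular shifts of each array within its replicons. The rank rule was tested on simulated data of 3 arrays and 23016 bins, where it recovered 4.5% of 200 raised bins at a log2 ratio of 1, 67% at 2 and 98.5% at 3, with 0 false calls. The Beta' bins named are from the 15 with the highest mean and the 5 with the lowest, without the called criterion of the rule. The interval without DNA was found by comparing input signal between the scan versions, and its edges by a running median over 5 probes. The rRNA repeat was found as the stretch from base 1 over which mean input signal at 19 probe starts shared by both chromosomes differed by a median of 0.065 (log2), against 1.05 at 36 shared starts after it. Its start was set at base 1, and only its other end was searched for. The further copy had an input profile correlated at 0.935 with the first, and the next best match reached 0.476.

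The array files name no genome build, and the gene table given is of assembly ASM332471v1. Its coordinates were not set against the arrays. It was used for gene names, for which genes neighbour each other, and for the number of rRNA operons and their place in the gene order of each chromosome, which were set against the repeats on the arrays. The planned tests over gene bodies, promoters, gene lists, reported RpoE targets and the RpoE motif need an annotation or sequence on the arrays' positions and were not run. Alternatives covered background correction, loess, quantile normalization, centring on the mode, the deposited ratios, dim probes, median over probes, bin width, the minimum change, separate fits, replicate and slide blocks and each replicate left out. Slide series was read from the leading digits of the array numbers and is not given by the labels. Scan batch, blocks in the tests against 0, the later scans alone and combinations with the deposited ratios were added after the data were examined. Calculations outside limma used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.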

Results

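Binding of the alternative sigma factor RpoE and of the Beta' subunit of the RNA polymerase core enzyme was measured along the genome of Rhodobacter sphaeroides, now named Cereibacter sphaeroides, a photosynthetic bacterium grown here with oxygen on succinate. The cells are labelled as carrying a deletion of chrR in all 6 libraries. ChrR is the anti-sigma factor that holds RpoE inactive. Chromatin immunoprecipitation with serum against RpoE gave 3 arrays, and serum against Beta' gave another 3. On each array the immunoprecipitated DNA was labelled with Cy5 and competed with input DNA labelled with Cy3. The 353081 genome probes, with a median spacing of 12 bp, covered 2 chromosomes and 5 smaller replicons. The median genome probe was 37.5 to 66.2 times as bright as the median random control probe in the Cy5 channel and 26.8 to 57.3 times as bright in the Cy3 channel. The labels do not say whether the 3 arrays of an antibody came from separate cultures, so p-values measure the spread between arrays, which may be technical, and their number limits the precision. Positions are those of the array files, whose genome build is not given in the sources used here.

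The deleted gene was examined first. On replicates 1 and 2 of both antibodies, 38 probes that span 523 bp of chromosome 1 (bases 2850156 to 2850678) gave input signal close to that of random probes. At most 3 of the 38 probes were above the 99th percentile of random probes in the input channel of any of these 4 arrays. The median input signal over this interval was 0.08 to 0.28 (log2) above the random-probe median on these 4 arrays, and between -5.76 and -4.57 relative to the median of its array. Of 46031 bins of 100 bp, 4 adjacent ones inside this interval had an input signal more than 2 (log2) lower on each of the 4 arrays than on both remaining arrays and a ChIP signal more than 1 lower. Probes that start at 2850145 and 2850639 overlap the ends of this interval. Their input signal was between -0.58 and 0.97 relative to the median of its array on these 4 arrays. The missing DNA may therefore be shorter than 523 bp. With all cells described as lacking ChrR, the interval was taken to hold the deleted part of chrR. Assembly ASM332471v1 lists rpoE, the gene of the sigma factor itself, as the direct neighbour of chrR.

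The 2 libraries labelled replicate 3 went against that description. In the library labelled RpoE replicate 3, input signal over the interval was 4.48 (log2) above the random probes and at -1.01 relative to the array median. In the library labelled Beta' replicate 3 it was 4.63 above the random probes and at -0.79 relative to the array median. Their ChIP channels were 5.93 and 3.30 above the random probes. These 2 arrays also carry another scanner software version than the other 4, so software version and any difference in cells cannot be told apart. Every mean over 3 arrays below includes a library that held this DNA. Values without it are given for some sites singly and for others only as a range.

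**Figure D1:**
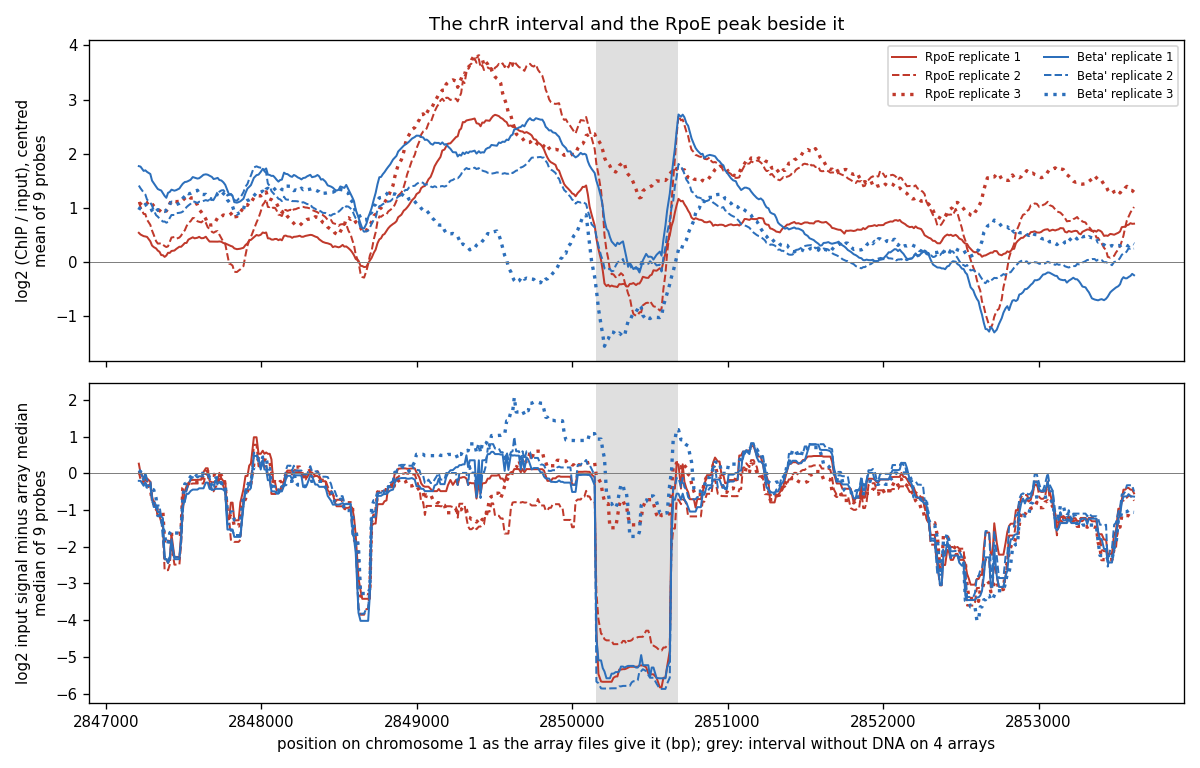
Log2 ratio of ChIP to input (upper panel, running mean of 9 probes) and log2 input signal minus the array median (lower panel, running median of 9 probes) against position on chromosome 1, for 3 RpoE arrays (red) and 3 Beta' arrays (blue). Over the grey interval (bases 2850156 to 2850678) input signal was between -5.76 and -4.57 relative to the array median on replicates 1 and 2, and at -1.01 and -0.79 in the RpoE and Beta' libraries labelled replicate 3.

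RpoE enrichment peaked directly beside this interval. The peak covered bases 2849001 to 2850200 of chromosome 1, with its summit between 2849401 and 2849600, 556 bp before the interval. The mean log2 ratio at the summit was 3.20 ± 0.51 (SD, n = 3), or 9.20-fold, and 3.09 without the library labelled replicate 3. Beta' at the same bin was 1.41 ± 0.87 (SD, n = 3), and 1.89 without the library labelled replicate 3, which alone gave 0.44.

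Which parts of the genome RpoE occupies was asked over 23016 bins of 200 bp. The strongest sites outside the rRNA operons, at bases 2343201 to 2343400, 744401 to 744600 and 211001 to 211200 of chromosome 1, had summit means of 3.65 ± 0.71, 3.64 ± 0.56 and 3.61 ± 0.25 (log2, SD, n = 3). These are 12.5-fold, 12.4-fold and 12.2-fold over input. Without the library labelled replicate 3 the means were 3.50, 3.42 and 3.64. On chromosome 2 the highest site, at 28801 to 29000, had 3.22 ± 0.69 (SD, n = 3). A site on plasmid P002, at 44801 to 45000, had 2.54 ± 0.57 (SD, n = 3). These and 6 further sites, 11 in all, met both of the following criteria. Their bins ranked in the highest 1% of bins on each of the 3 RpoE arrays, and at least 1 bin passed the limma test in the authors' deposited ratios, where the lowest adjusted p per site was 0.00663 to 0.0242. Both criteria rest on the same 3 RpoE arrays, so meeting both is not independent support. Their summit means were 1.84 to 3.65, and 1.83 to 3.64 without the library labelled replicate 3. The remaining sites had summits on chromosome 1 at 446201 to 446400 (2.94 ± 0.72, SD, n = 3), 642401 to 642600 (2.20 ± 0.79) and 1668201 to 1668400 (1.93 ± 0.78), at 3186401 to 3186600 (2.03 ± 0.72), and on chromosome 2 at 146001 to 146200 (1.84 ± 0.56), besides the peak beside the chrR interval. No gene is named for any of them but the last, since no annotation on the positions of the array files was at hand.

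Beta' was not equally present at these sites. Its mean was above 2-fold at 5 of the 11 summits. The highest was 1.97 ± 0.51 (SD, n = 3) at 744401 of chromosome 1, and 1.73 ± 0.89 was measured at 2343201. Without the library labelled replicate 3 these Beta' means were 2.18 and 2.15. At 3 sites it was below 1.5-fold. These were the plasmid P002 site (0.20 ± 0.18, SD, n = 3), the chromosome 1 site at 3186401 (0.37 ± 0.18) and the chromosome 2 site at 146001 (0.40 ± 0.05). At the site at 211001 the Beta' mean of 1.04 ± 0.77 (SD, n = 3) rested on the library labelled replicate 3, at 1.92, and was 0.61 without it. Leaving that library out raised the Beta' mean from 0.82 to 1.06 at 642401 of chromosome 1 and from 0.91 to 1.06 at 28801 of chromosome 2, past 2-fold. At 10 of the 11 sites the lowest RpoE array exceeded the highest Beta' array, which chance gives at 5% of places with 3 against 3 arrays. The sites were chosen for high RpoE ratios, so this count is not independent of the choice. An exact two-sided permutation test between antibodies cannot go below p = 0.1 with 3 arrays each.

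**Figure D2:**
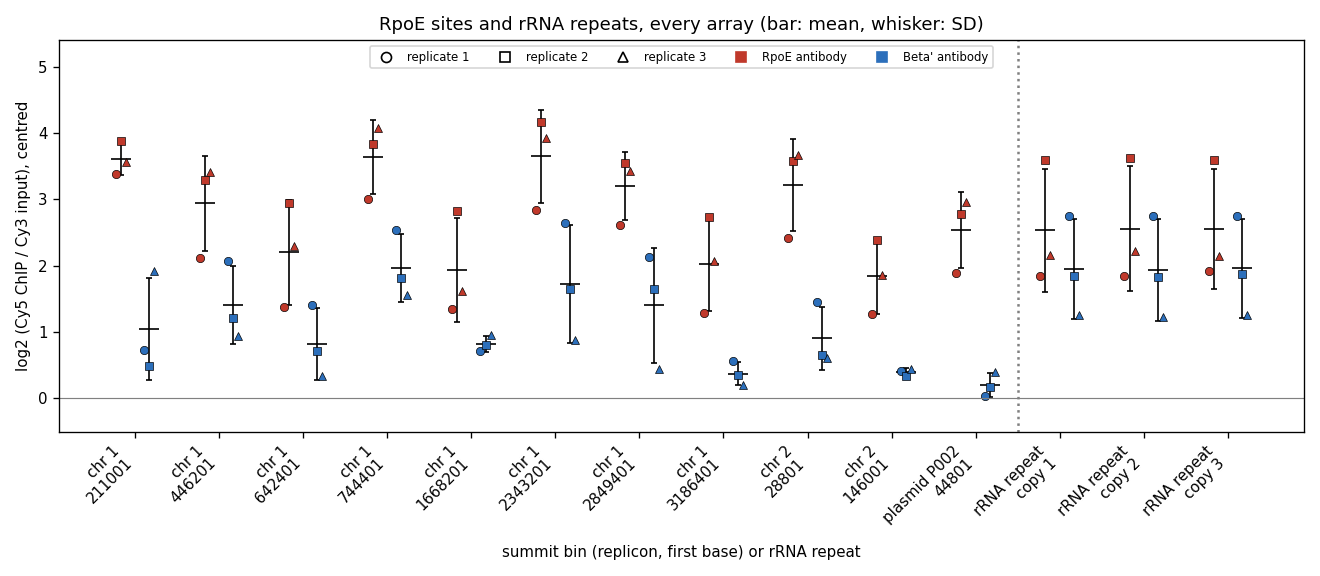
Log2 ratio of ChIP to input at the summit bin of 11 RpoE sites and the median over each of 3 rRNA repeat copies (horizontal axis), for every array. Red symbols are RpoE and blue symbols Beta', shapes give the replicate, bars the mean of 3 arrays and whiskers the SD. RpoE summit means run from 1.84 to 3.65 and Beta' means at the same bins from 0.20 to 1.97.

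The planned test called none of these sites. With limma's treat against a 1.5-fold change, 0 of 23016 bins passed for RpoE at an adjusted p of 0.05, and the lowest adjusted p was 0.0542, while 172 bins had an unadjusted p below 0.05. Adding scan batch as a block, with equal weight per batch, gave 6 bins. Slide series as a block gave 100, with a lowest adjusted p of 0.00356 in the treat test and 2 residual degrees of freedom. Plain eBayes against no change called 12 bins, and the deposited ratios, which the authors had quantile normalized, gave 48 bins in 14 regions under the treat test. Of these 48 bins, 46 ranked in the highest 1% on all RpoE arrays of the scanner ratios, which come from the same arrays and give no separate support. Without RpoE replicate 1 or the library labelled RpoE replicate 3, the deposited ratios gave 0 calls. The median SD between RpoE arrays was 0.26 over all bins and 0.69 at the summits of the 11 sites. The ranking, chosen after the data were examined, gave 103 RpoE bins, against a mean of 0.024 and at most 18 in 10000 random circular shifts of the arrays (permutation p = 1e-04, one-sided, the smallest the shifts can give). The shifts break any profile that the arrays share, so this p-value does not separate RpoE binding from a shared background. Of the 103 bins, 72 lay in the rRNA repeats, whose copies these probes cannot separate. Of all 14 sites found by rank outside the rRNA operons, 12 had a lower mean input signal on the RpoE arrays than on the Beta' arrays, with a median difference of -0.77 (log2) over the 14, which adds to the ratio. In the ChIP channel alone the median summit lay 1.96, 2.25 and 2.50 above the array median on the 3 RpoE arrays and 1.84, 1.34 and 1.42 above it on the 3 Beta' arrays, so part of the difference in ratio between antibodies came from the input channel.

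The rRNA operons carried high signal with both sera. A block of 5669 bp at the first bases of chromosome 1 and of chromosome 2 had near-identical probe signal, and a further copy lay at bases 33677 to 39345 of chromosome 2. They were taken as the rRNA operons because the assembly named above lists 3 such operons, with rRNA genes first in gene order on both chromosomes, and no sequence was at hand to test this. Over the copy at 33677 the median RpoE ratio was 2.55 ± 0.91 (SD, n = 3) and the median Beta' ratio 1.96 ± 0.75 (SD, n = 3). The copies at the start of chromosomes 1 and 2 had RpoE medians of 2.53 and 2.56 and Beta' medians of 1.95 and 1.93. The copies share sequence and cannot be separated by these probes. Of the 103 RpoE bins by rank, 72 lay in the repeats, and so did 24 of the 48 bins called in the deposited ratios. For Beta', 0 of the 11 bins by rank and 0 of the 20 bins called in the deposited ratios lay there. Bins just before the start set for a copy count as outside, and both sets hold such bins. In the library labelled Beta' replicate 3 the median over the copy at 33677 was 1.26, below the 99th percentile of that array, 2.35. This contrast rested on that library. Without the libraries labelled replicate 3, 79 of 132 Beta' bins by rank and 73 of 155 RpoE bins by rank lay in the repeats. Over the copy at 33677 the medians were 1.92 and 3.59 on RpoE replicates 1 and 2 and 2.75 and 1.87 on Beta' replicates 1 and 2, each above the 99th percentile of its array, 0.83, 2.17, 2.19 and 1.22.

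In the mean of 3 arrays Beta' was highest just before it. The bins at 33201 to 33400 and 942601 to 942800 of chromosome 2 and 3188201 to 3188400 of chromosome 1 end 276, 238 and 231 bp before the start set for a copy, counting the chromosomes as circles. That start rests on base 1, which was set and not searched for. The bins at 942601 and 3188201 had close values on every array, so the shared sequence may begin before it. Per the labels' protocols, fragments were 500 bp long after the nuclease, more than the distances given. Signal at the 3 bins is therefore not resolved from signal inside a copy. These 3 bins had the 3 highest Beta' means of all bins, at 2.86 ± 0.82, 2.75 ± 0.52 and 2.70 ± 0.55 (log2, SD, n = 3). Their RpoE means were 1.31 ± 0.72, 1.65 ± 0.77 and 1.59 ± 0.80. These places rested in part on the library labelled Beta' replicate 3. Without it the bins ranked 14, 3 and 4 and had 2.52, 2.63 and 2.59. The highest bins inside the copies beside them then had 2.63, 2.58 and 2.58. The bin at 33401 to 33600 of chromosome 2, also before the start set for a copy, then had 2.66. RpoE followed 2 broad stretches inside the repeat with a dip between them. At the inner bin with the lowest Beta' mean, RpoE fell by 1.42 ± 0.25 (log2, SD, n = 3) relative to the rest of the repeat and Beta' fell by 0.43 ± 0.33 (SD, n = 3). On replicates 1 and 2 alone RpoE fell by 1.38 and 1.69, and Beta' fell by 0.63 and 0.61. The dip was larger on every RpoE array than on every Beta' array, at p = 0.1 in an exact two-sided permutation test, the smallest that 3 against 3 allows.

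**Figure D3:**
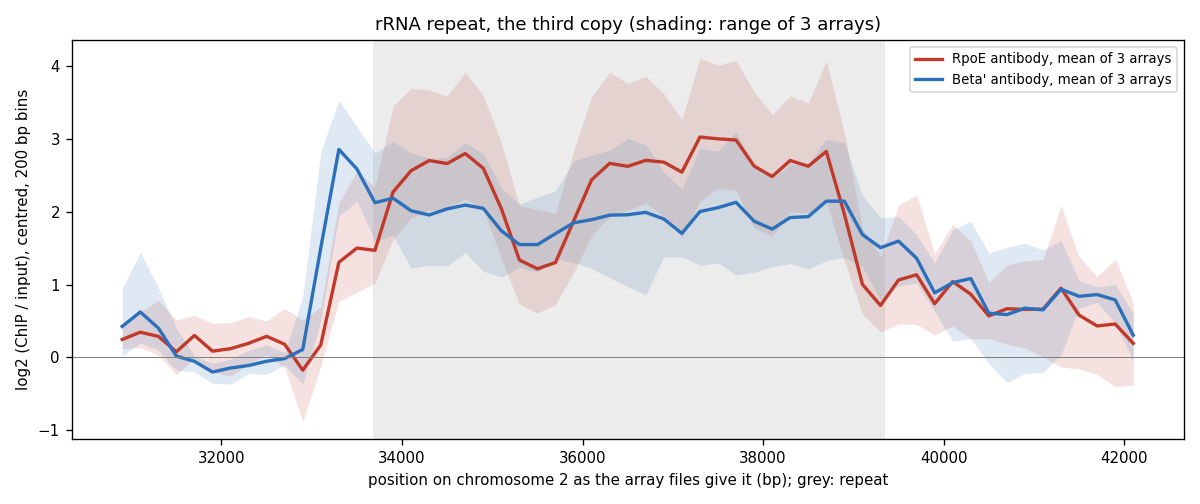
Log2 ratio of ChIP to input in 200 bp bins (vertical axis) against position on chromosome 2 around the rRNA repeat copy at 33677 to 39345 (grey), as the mean of 3 RpoE arrays (red) and 3 Beta' arrays (blue) with the range of the arrays shaded. The Beta' mean is highest before the repeat, at 2.86, where RpoE is 1.31. Without the library labelled replicate 3 it is 2.52 in that bin, 2.66 in the next bin, also before the repeat, and up to 2.63 inside it.

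Where the core enzyme itself was enriched was asked in the same way with the Beta' arrays. Outside the bins before the rRNA repeats, the highest Beta' means lay on chromosome 1 at 2916001 to 2916200 (2.60 ± 0.67, SD, n = 3), 1401001 to 1401200 (2.53 ± 1.01), 479801 to 480000 (2.51 ± 0.60), 2741601 to 2741800 (2.45 ± 1.05) and 1837201 to 1837400 (2.43 ± 0.73). RpoE means there were 1.10 ± 0.91, 0.79 ± 0.98, 0.72 ± 0.76, 0.84 ± 0.44 and 0.97 ± 0.63 (SD, n = 3). Without the libraries labelled replicate 3 the Beta' means were 2.32, 1.98, 2.35, 1.96 and 2.11, and each stayed above the RpoE mean of the same bin. The bins were chosen for high Beta' means, so this is not independent of the choice. Single arrays overlapped: RpoE replicate 2 exceeded Beta' replicate 2 at 2916001 (2.12 against 1.86), 1401001 and 1837201, but not at 479801 or 2741601. The highest bin of a plasmid among the 15 highest was at 89801 to 90000 of plasmid A (2.25 ± 1.22, SD, n = 3), where the library labelled replicate 3 gave 3.54 and the others 2.10 and 1.12. The lowest Beta' mean of any bin was -0.64 ± 0.15 (SD, n = 3) at 812601 to 812800 of chromosome 2. The median bin of each replicon lay between -0.12 and 0.13 in the Beta' mean.

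For Beta' the limma treat test called 0 bins in the scanner ratios, with a lowest adjusted p of 0.546 and 489 bins at an unadjusted p below 0.05. Plain eBayes called 1 bin. The deposited ratios gave 20 bins in 15 stretches. Of these bins, 8 were among the 11 that ranked in the highest 1% on all Beta' arrays, which are the same arrays. The 11 bins compare with a mean of 0.021 and at most 5 in the circular shifts (permutation p = 1e-04, one-sided, the smallest possible). As for RpoE, this does not separate binding from a shared background. The library labelled Beta' replicate 3 set this number, since 132 bins ranked in the highest 1% on both other arrays. The deposited count moved with every Beta' array, to 1, 2 and 184 bins without replicates 1, 2 and 3.

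RpoE was compared with Beta' directly, to separate promoters held by this sigma factor from those of the polymerase in general. The limma treat test called 0 bins in either direction, with 41 bins at an unadjusted p below 0.05, and plain eBayes called 0. The largest difference at the 11 sites was 2.57 (log2) at 211001 of chromosome 1, where RpoE was 3.61 and Beta' 1.04, and the plasmid P002 site differed by 2.34. The smallest was 1.11 at 1668201. In the deposited ratios the lowest adjusted p for a difference at these summits was 0.804. With scan batch as a block, the scanner ratios gave 0 calls for the difference, as did the later scans alone. The earlier scans hold 1 array per antibody and allow no test of their own. In the deposited ratios 0 of the 14 RpoE regions held a called Beta' bin. With any change from 0, over all arrays, 16 of 30 regions in the deposited ratios did, against a mean of 2.17 in circular shifts of the Beta' calls. On the later scans alone 21 of 27 regions did. But the 4 arrays of the later scans, which enter both counts, share a profile across antibodies, with r from 0.585 to 0.766 over bins of the deposited ratios. The overlap is therefore not separate evidence.

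In their ratios the arrays of the later scans resembled one another across antibodies, and the 2 libraries labelled replicate 3 were close neither to them nor to each other. In input signal those 2 libraries correlated at 0.986 with each other and at 0.939 to 0.962 with the later scans. Across bins, which are not independent replicates, Pearson's r was 0.757 between RpoE replicates 1 and 2 and 0.767 between Beta' replicates 1 and 2. It was 0.851 between RpoE replicate 1 and Beta' replicate 2 and 0.828 between RpoE replicate 2 and Beta' replicate 1. The library labelled RpoE replicate 3 reached 0.308 and 0.114 with the other RpoE arrays and 0.200 with the library labelled Beta' replicate 3. The SD of bin ratios was 0.24, 0.68 and 0.35 on RpoE replicates 1 to 3 and 0.57, 0.31 and 0.60 on the Beta' arrays.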

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

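The 0 RpoE and 0 Beta' calls of the limma treat test held with mode centring, bins of 100 and 500 bp, a 2-fold minimum, each antibody fitted alone and the later scans alone. RpoE calls became 2 bins with normexp, 10 bins (3 regions) with loess, 83 (16 regions) with quantile normalization, 48 (14 regions) with the deposited ratios, 7 (2 regions) without dim probes, 6 (2 regions) with the median over probes and 12 (4 regions) with any change from 0. Beta' calls became 29 bins with quantile normalization, 20 with the deposited ratios and 1 with any change from 0. Added after the data were examined, the deposited ratios gave 161 RpoE bins (27 regions, 21 with a Beta' bin) and 384 Beta' bins on the later scans alone, and 159 (30 regions, 16 with a Beta' bin) and 742 with any change from 0, counting bins above 0, with 1 RpoE bin and 97 Beta' bins below 0. The cause of these differences was not tested. With each replicate left out, scanner ratios gave 0 to 5 RpoE bins (0 to 2 regions) and 0 Beta' bins, the 5 being without the library labelled Beta' replicate 3. The deposited ratios gave 0, 15 and 0 RpoE bins (0, 5 and 0 regions) without RpoE replicates 1, 2 and 3, and 23, 55 and 106 (7, 14 and 18 regions) without Beta' replicates 1, 2 and 3. Beta' bins in the same order were 8, 14 and 31, then 1, 2 and 184. The difference between antibodies gave 0 calls in every setting run.

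The replicate block also gave 0 calls for the difference, as did the slide series block and the scan batch block. For RpoE against 0, taking blocks with equal weight, the replicate block gave 0 bins, the slide series block 100 (15 regions) and the scan batch block 6 (2 regions), and for Beta' all 3 gave 0. In the deposited ratios the scan batch block gave 108 RpoE bins (18 regions) and 162 Beta' bins. These fits against 0 were added after the data were examined, and the cause was not tested. Same-numbered arrays deviated from their group means with correlations of -0.466, -0.067 and 0.482 across bins, and RpoE replicate 2 correlated best with Beta' replicate 1, at 0.696, so the numbers were not taken to pair the arrays. The 2 libraries labelled replicate 3 share a scan version.

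The 103 RpoE bins by rank were 100 to 107 under the other ways of making ratios and 135 at the highest 2%, and became 221 at the highest 5%. With each RpoE replicate left out they were 105 to 155, a number that cannot fall when fewer arrays must rank high. The 11 Beta' bins became 53 and 245 at the highest 2% and 5% and were 12 to 132 with each Beta' replicate left out. Of 84 RpoE summit values at the 14 sites by rank under other settings, 83 moved by less than 1 SD and 0 changed sign. The mode of the library labelled Beta' replicate 3 lay at -0.12 (log2), so mode centring raised its values by that amount. The other arrays moved by less than 0.1. The alternatives listed for gene bodies, promoters, gene lists, reported targets and the motif were not run, for want of an annotation on the arrays' positions. The median genome probe was at least 26.8-fold over random probes. The simulated test of RpoE against 0 made calls with 3 arrays, but its raised bins were drawn at random and kept their own fitted spread. The median SD between RpoE arrays was 0.26 over all bins and 0.69 at the 11 summits. The simulation therefore cannot tell whether the number of arrays set that 0 count. The other tests were not simulated.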

Other observations

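A stretch of 26 kb on chromosome 1, bases 1680001 to 1706000, differed in input signal between the scan versions, which also separate libraries with and without DNA of the chrR interval. Its input signal was 2.01 and 1.57 (log2) above the array median in the libraries labelled Beta' and RpoE replicate 3, and 0.066 to 0.82 above it on the other 4 arrays. Its ratio was 2.65 and 0.93 on Beta' replicates 1 and 2, but -0.87 in the library labelled Beta' replicate 3. On the RpoE arrays it was 0.55, 1.96 and 0.35. A stretch of 4 kb on plasmid P003, bases 51001 to 55000, had ratios of 2.11 and 1.27 on Beta' replicates 1 and 2 and -1.01 in the library labelled replicate 3. Among the 3 sites by rank that the deposited ratios did not call, 2 were bins just before rRNA repeats and the last, at 1030201 to 1030400 of chromosome 1, had Beta' ratios of 1.30, 0.68 and 3.39.

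Of the tests below, the replacement of input signal and the comparison with the earlier Beta' array were fixed before their results were seen, and the others were chosen after. For RpoE against Beta', the real grouping gave 0 calls and the highest of the other splits gave 0, so all 10 splits gave as many, and 10 splits are too few for a share under 0.05.

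The DNA of the chrR interval in the 2 libraries labelled replicate 3 was the first pattern. Input DNA alone from cells with the gene is argued against, because the ChIP signal over the interval was at least 1.72 (log2) above the 99th percentile of random probes in both. If ChIP and input came from the same cells with an intact gene, the ratio over the interval should follow its flanks, provided that occupancy is alike over both. In the library labelled RpoE replicate 3 it was -0.30 against the flanks, inside the central 95% of 12228 like windows (-0.51 to 0.55). In the library labelled Beta' replicate 3 it was -1.64, outside the range of -0.82 to 1.16. Lower Beta' occupancy over the interval in the same cells would give this too. The ratio of that library was also negative before the interval, at -0.70 for the probe at 2849606. The value therefore cannot tell whether both channels of that array held equal cells. Cells with the gene, a mixture of cells and a sample exchanged with another strain may each account for the DNA of the interval, and a biological explanation was not tested.

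High RpoE signal over the rRNA repeats was the second pattern. Whether RpoE signal simply follows Beta' was not settled by 83 other bins with as high a Beta' mean. The rRNA medians were 1.84, 3.59 and 2.17 on the 3 RpoE arrays against medians of 0.52, 1.27 and 0.21 over those bins, but the smallest excess over the upper end of the central 95% of those bins was -0.95. When the 6 of those bins that are RpoE bins by rank were left out, it was 0.78. Those 6 were picked by their high RpoE values, so a rise was bound to follow and gives no support. Competition between the dyes stays open too: with the highest input signal of the 6 arrays in place of its own, the rRNA median of RpoE replicate 2 lay -0.81 from the array's highest 1%, while the other 2 RpoE arrays stayed above theirs. Inside the repeat RpoE did not follow the Beta' profile: the RpoE dip minus the Beta' dip was -0.99, with all 3 RpoE arrays below all 3 Beta' arrays. This argues against polymerase travelling along the operons as the whole source of the RpoE ratio. The argument is limited by an exact two-sided permutation p of 0.1, the smallest possible, and by the input effects left open above. Signal tied to the mature rRNA stretches may be a candidate source, untested here, as is binding of RpoE itself.

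The profile shared by both antibodies on the later scans was the third pattern. The later scans are also the arrays without DNA of the chrR interval, so scan batch and any difference in cells cannot be told apart here. An intensity-dependent dye bias as the whole cause is argued against, since the lowest correlation between antibodies among later scans was 0.574 after loess, against 0.192 between the libraries labelled replicate 3. The authors' normalization is not needed for this profile, which was seen in the scanner ratios, where the lowest such correlation was 0.686. This restates the observation and is no separate test. Polymerase occupancy recovered with both sera cannot be told apart from a shared background: the mean Beta' profile of the later scans correlated at 0.196 with the earlier Beta' array, between the bounds set beforehand, and no array without antibody was analysed here.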
